A study of Mus musculus with 15 samples.

How the data were processed

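RNA from mouse spermatogonial stem cell cultures was measured on 15 single-colour Affymetrix arrays, 1 array per sample, in 5 groups of 3. The labels give the groups, and every sample was used. Per the labels, the authors computed the signal with MAS5, the Affymetrix algorithm that combines the probes of a probe set into 1 value. The deposited values are therefore MAS5 signal, an intensity on a linear scale, for 45101 probe sets on each array. The version of MAS5, the chip, the genome build and the scaling target are not given in the sources used here. From the values themselves, the mean of the middle 96% of probe sets was 150 on each array, so every array had been scaled to 1 trimmed mean by the authors. Median signal per array ran from 42.5 to 55.8, and 26 single values were exactly 0. No 2 arrays were identical, and Pearson's r between arrays, across probe sets, lay between 0.936 and 0.974. The number of arrays per group limits the precision of every comparison: the median standard error of a log2 difference was 0.19.

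Probe sets were named from the platform's own annotation. Of the 45101, 34958 carried 1 gene symbol, 932 carried several and 9211 carried none. The reference annotation was used only to look up symbols: it held the symbols of 34754 probe sets and changed 0 of them. Control probe sets, 64 in number, were kept out of the tests. Signals were transformed as log2 of signal plus 16. The dimmest 40% of probe sets by mean log2 value over the 15 arrays, those under a signal of about 30.5, were left out, which kept 27022. Of these, 4154 with several symbols or none were tested apart and are not named. A gene was represented by its probe set with the highest mean on the log2 scale with the constant of 16, which gave 13083 genes and need not be the probe set with the highest mean signal. For 5804 of them more than 1 probe set had passed the filter, and for the genes named in every comparison the results say where another probe set gave another call on withdrawal or at 8 h of replacement, adjusted over all probe sets. The constant of 16 draws dim signals together, so folds of dim genes are smaller than the ratio of the mean signals printed beside them. Where the lower group lay under a signal of 30.5, the fold and its rank depend on that constant.

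Group means were fitted for all 5 groups together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend on mean intensity and no robust option), with 10 residual degrees of freedom. Of the 6 comparisons, 4 were those of withdrawal against maintained cultures and of each replacement time against withdrawal. The others set 8 h of replacement against maintained cultures and against 2 h of replacement. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg's method over the 13083 genes of a comparison, and a gene was called at an adjusted p under 0.05. Counts at a fold of at least 2 are given beside. Values printed with ± are the mean and SD of signal on the linear scale over 3 arrays. Folds and log2 differences are limma estimates on the log2 scale.

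Gene lists were fixed before the data were examined, as were the comparisons, the test, the rule for naming genes and the first set of alternatives. The 20 lists held 394 distinct genes, of which 325 were tested. They cover genes that the laboratory has named as regulated by GDNF (glial cell line-derived neurotrophic factor), undifferentiated and differentiating spermatogonia, meiotic and haploid germ cells, pluripotency, ERK immediate-early and feedback genes, FOXO target genes, and GDNF and FGF family ligands and receptors. Further lists cover G1/S and G2/M of the cell cycle, ribosome biogenesis and MYC targets, cholesterol synthesis, glycolysis, the amino acid and ATF4 response, p53 and apoptosis, and the interferon response. The last 4 hold markers of other cells that such cultures may contain: fibroblasts, Sertoli cells, Leydig and peritubular cells, and endothelial and blood cells. The first list came from work that drew on these arrays. Some lists share genes. Bcl6b, Etv5 and Lhx1 of the first list are also in the undifferentiated list, and Egr2, Egr3 and Etv5 are also in the ERK list. Egr4, Etv4 and Etv5 are in both the undifferentiated and the ERK list. Each list was tested with camera in limma, which compares its genes with all other genes, at a preset correlation of 0.01. P-values were adjusted over the 20 lists within a comparison. The test was repeated with a correlation estimated from the arrays. Calls of single members are also given "adjusted over the list alone", that is, with the correction made within 1 list.

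Genes were named by a rule. In each of the 4 main comparisons these were the 8 largest rises and the 8 largest falls among called genes whose groups of arrays did not overlap, with clone identifiers skipped. In the other comparisons 5 were taken each way. Up to 4 called members of each list were added, and the genes of the first list together with Gfra1, Ret, Id4, Zbtb16, Pou5f1, Kit and Stra8 were named whatever their result. Some further list members and genes are named in the text because of their values, and were chosen after these were seen: other called members of a list, Trib1, Plk3, Ier2, Junb, Zfp36, Cma1, Cpa3, Adm, Ankrd37, Hsph1 and Chordc1 where the rule does not reach them.

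The alternatives tried were a constant of 1 or 64 in place of 16, no filter, a filter at 60%, quantile normalization, shifting all arrays to 1 median, the mean of a gene's probe sets, every probe set on its own, a fit without the variance trend, a robust trend, a replicate block, a fit of only the groups compared, leave-one-out of each array, and the estimated correlation for lists. Not all were applied to the lists. The lists were not tested with the mean of probe sets, every probe set, no variance trend, the robust trend or only the groups compared. Of the arrays, only withdrawal replicate 3 and 2 h replicate 3 were left out for lists. Alternatives added after the data were seen were array weights, the mean of the fibroblast list as a covariate, the ratio of 3' to 5' beta-actin control signal as a covariate, leaving out withdrawal replicate 3 in comparisons that do not contain it and for the lists, and leaving out 2 h replicate 3 for the lists. The fibroblast list was not tested as a list under its own covariate, since that is circular. Single members of it were fitted with the others, and their values under that covariate carry no information, because it removes their shared change by construction.

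The fit was tested on simulated data built on the arrays of withdrawal and maintained cultures. Of 50 genes each shifted by a log2 of 0.5, 1, 2 or 3, the fit called 18%, 60%, 98% and 100%, with 9 false calls among 147. A simulated list of 25 genes shifted by 0.5 was called by camera, and an unshifted list was not. The simulated genes were independent of each other. This check therefore does not show how often camera calls unshifted lists of correlated genes. Because the withdrawal arrays enter both the withdrawal and the replacement comparisons, the overlap of calls was set against 100 simulated draws with no true differences and the same sharing. Such draws leave hardly any gene to be called, so they cannot show how much overlap the sharing adds to true changes. The labels do not say whether replicates are separate cultures, so p-values may measure technical spread.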

Results

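Gene expression was measured in cultures of mouse spermatogonial stem cells, the germline stem cells of the testis, derived from C57BL/6 males aged 6 days. The cells depend in culture on GDNF, a growth factor that signals through the receptor RET and its co-receptor GFRalpha1, and the serum-free medium held both GDNF and soluble GFRalpha1 together with bFGF. Maintained cultures had these factors throughout. Withdrawal cultures went 18 h without GDNF and GFRalpha1. In the replacement groups both were given back after that time, for 2, 4 or 8 h. The labels name no group kept without the factors beyond 18 h, and none handled alike but not given them. The return of the factors therefore cannot be told apart from handling or from added time in culture. Each of the 5 groups had 3 arrays, 15 in all, and the values are MAS5 signal in arbitrary units. The number of arrays limits the precision. The labels do not say that replicates were separate cultures, so the spread between arrays may be technical only. With 3 arrays against 3, an exact rank test cannot give a p under 0.1, so calls rest on limma, which pools the spread over genes. Unless stated otherwise, n = 3 in each group and p-values are adjusted over 13083 genes.

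The first comparison asked which transcripts changed when GDNF and GFRalpha1 were taken away. After 18 h of withdrawal Bcl6b, Etv5, Id4 and Lhx1, known for roles in the stem cell state, fell, and so did most ERK immediate-early and feedback genes. Bcl6b, a transcriptional repressor used in stem cell self-renewal, was at 92.9 ± 25.3 against 630 ± 143 in maintained cultures, 5.94-fold lower (adjusted p = 8.68e-06). Etv5, an ETS transcription factor, was at 354 ± 71.4 against 1108 ± 370, or 2.96-fold lower (adjusted p = 0.000441). Id4, an inhibitor of DNA binding that marks stem cells, was at 362 ± 86.1 against 1301 ± 207, or 3.53-fold lower (adjusted p = 1.56e-05). Lhx1, a LIM homeobox factor, fell 3.86-fold and Egr2, an immediate-early zinc finger factor, fell 4.99-fold. The transcripts of Gfra1, the GDNF co-receptor, were at 810 ± 82.2 against 1496 ± 114, or 1.83-fold lower (adjusted p = 0.0124).

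Of the 13083 genes, 1052 were called, 551 higher and 501 lower, and 230 of them changed at least 2-fold, 102 up and 128 down. The largest falls also included the heparan sulfate enzyme gene Hs3st3b1 (5.73-fold), the kinase gene Nim1k (4.98-fold), the ETS factor Etv4 (4.76-fold), the pluripotency factor Sox2 (4.55-fold, 37.3 ± 9.39 against 224 ± 10.2), the lysosomal regulator Tfeb (4.5-fold) and the circadian repressor Bhlhe40 (4.5-fold). The largest rises were Zmym3 at 819 ± 120 against 124 ± 25.3 (5.99-fold), Camk2n1, an inhibitor of CaM kinase II, at 875 ± 129 against 152 ± 10.2 (5.26-fold), and Rspo1, a WNT agonist (5.14-fold). They were followed by Rragd, a GTPase of mTORC1 nutrient sensing (4.24-fold), Kif26a (4.14-fold), Igfbp6 (3.8-fold), the estrogen receptor gene Esr1 (3.79-fold) and Nos1ap (3.5-fold). Kif26a varied widely, at 112 ± 114 after withdrawal against 7.27 ± 4.18. For Nim1k, Kif26a, Esr1 and Nos1ap the lower group lay under a signal of 30.5, so their folds and ranks depend on the constant of 16.

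Of the 8 genes that the laboratory has named as GDNF-regulated, 6 fell: Bcl6b, Etv5, Lhx1, Egr2, the chemokine receptor Cxcr4 (4.4-fold) and the POU factor Pou3f1 (2.22-fold). The count adjusted over the list alone was also 6. The list was chosen on these samples and is not independent evidence of its direction (median log2 difference -1.76, camera adjusted p = 1.67e-12). Egr3 and Tspan8 were not called on the probe sets chosen for them, at log2 differences of 0.01 and -0.14. Another probe set of each was called lower, at a log2 of -1.54 for Egr3, where it has the higher mean signal (143 against 120), and -2.0 for Tspan8. Egr3 was also called lower with a constant of 64 and with the mean of its probe sets. Conversely, a dimmer probe set of Egr2 (log2 -1.22), of Pou3f1 (log2 -0.35) and of Etv5 (log2 -1.28) was not called. Of 33 ERK immediate-early and feedback genes, 21 fell and 1 rose (adjusted over the list alone, 21 and 2), with a median of -0.76 and an adjusted p of 2.35e-17. Among them were Dusp6, an ERK phosphatase, at 338 ± 98 against 1123 ± 434 (3.15-fold lower), the feedback inhibitor Spry2 (3.39-fold lower), Myc (log2 -1.61) and Fos (log2 -0.98). The member that rose was Egr4 (log2 1.19).

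Members of the undifferentiated spermatogonia list moved both ways. Of 27, 10 fell and 6 rose (adjusted over the list alone, 11 and 7), and the list was not called (median -0.05, adjusted p = 0.0703). Gfra1, Id4, Eomes (log2 -1.13), Epcam (log2 -1.08), Itga6 and Cd9 fell, together with Bcl6b, Etv4, Etv5 and Lhx1. Neurog3 (2.98-fold) and Sox3 (3.12-fold), factors of progenitors that leave the stem cell pool, rose, as did Upp1 (3.24-fold), Egr4 (2.29-fold), Foxo1 (1.68-fold) and Zbtb16 (1.71-fold, 2468 ± 583 against 1414 ± 32.7, adjusted p = 0.0261). Of 14 differentiating spermatogonia genes, 4 rose and 1, Ccnd3, fell (adjusted over the list alone, 5 and 2), without a call for the list (median 0.19, adjusted p = 0.126). Those that rose were Sohlh1, a germ cell factor of early differentiation (277 ± 94.2 against 94 ± 7.97, 2.59-fold), Lmo1, Dnmt3a and Dmrt1. The other 2 probe sets of Gfra1 (log2 -1.31 and -1.42) and 1 of the other 2 of Zbtb16 (log2 0.71) were not called. Kit and Stra8, classical markers of differentiation, were not called, at log2 differences of 0.10 and -0.66. Pou5f1 was not called (log2 0.35), nor was Ret (log2 -0.05), although a second Ret probe set was lower by a log2 of -0.87.

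Cholesterol synthesis genes fell as a group. Of 17, 12 fell and none rose (adjusted over the list alone, 16), with a median of -0.76 and an adjusted p of 8.87e-17. Msmo1, a sterol oxidase, was at 919 ± 166 against 2375 ± 167 (2.58-fold lower), Pmvk was 2.26-fold lower, Nsdhl 2.15-fold and Cyp51 2.1-fold. Of 24 G1/S genes, 8 fell and none rose (adjusted over the list alone, 11), with a median of -0.36 and an adjusted p of 1.51e-07, or adjusted p = 0.107 with an estimated correlation. Examples were Pcna, the DNA polymerase clamp, at 3096 ± 978 against 6554 ± 779 (2.18-fold lower), the ribonucleotide reductase gene Rrm2 (2.67-fold) and the cyclins Ccne2 (2.06-fold) and Ccne1 (2-fold). Among 21 G2/M genes only Cdk1 was called (1.62-fold lower), also when adjusted over the list alone, and the median was -0.01 (adjusted p = 0.608), turning to 0.03 with quantile normalization. In the glycolysis list, Hk2 (2.01-fold) and the glucose transporter gene Slc2a3 (1.99-fold) fell and Hk1 rose (1.37-fold), out of 14; adjusted over the list alone, 5 fell and 1 rose. The median was -0.49 (adjusted p = 0.00667), and adjusted p = 0.436 with an estimated correlation.

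Of 21 FOXO target genes, 5 were higher and 1 lower (adjusted over the list alone, 8 and 1), and the list was called higher with a median of 0.14 (adjusted p = 0.00968). This call was lost at adjusted p = 0.262 with an estimated correlation. The ubiquitin ligase gene Fbxo32 was at 543 ± 39.4 against 175 ± 30.9 (2.94-fold higher), Ddit4, an mTORC1 inhibitor, rose 2.37-fold and Txnip rose 1.87-fold, with Klf2 and Pink1 also higher, whereas Gadd45a fell 1.57-fold. Of 14 pluripotency genes, Sox2, Tcl1 (2.13-fold) and Dppa4 (1.44-fold) fell and Klf2 rose, with the same counts adjusted over the list alone. The median of that list was 0.23 although its mean was -0.06 and its test pointed down (adjusted p = 0.601). Of 20 GDNF and FGF family genes, Fgf9 (2.95-fold) and Gfra1 fell and Gfra3 rose (2.09-fold); adjusted over the list alone, 2 fell and 2 rose. Their median was 0.01 with a mean of -0.04 (adjusted p = 0.668), and the median became -0.04 with quantile normalization and -0.08 with arrays shifted to 1 median.

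The remaining lists were not called on withdrawal. Of 26 ribosome biogenesis and MYC target genes, Nop58 (1.55-fold) and Srm (1.42-fold) fell, with a median of 0.03 and a mean of -0.02 (adjusted p = 0.608); with arrays shifted to 1 median the median was -0.06. In the amino acid and ATF4 list of 21, Psat1 (1.54-fold) and Asns (1.44-fold) fell and Trib3 rose 1.81-fold (adjusted over the list alone, 4 and 2), with a median of -0.10 (adjusted p = 0.143). Of 19 p53 and apoptosis genes, Bik rose 1.98-fold and Gadd45a fell (median -0.11, adjusted p = 0.601). Of 11 interferon genes, Oasl2 rose 2.61-fold, with a list median of 0.08 (adjusted p = 0.574) that became -0.02 with quantile normalization and -0.01 with arrays shifted to 1 median. For the ribosome, p53 and interferon lists the counts adjusted over the list alone were the same. None of the 16 meiotic and haploid genes was called in limma (median -0.05, adjusted p = 0.574), and the same held for 12 Sertoli cell genes (0.16, adjusted p = 0.525), 5 Leydig and peritubular genes (0.21, adjusted p = 0.53) and 9 endothelial and blood cell genes (0.16, adjusted p = 0.68). The fibroblasts list of 18 genes had a median of -0.08 (adjusted p = 0.355). Without withdrawal replicate 3 it was called, with a median of -0.32, and so were the amino acid and ATF4 response (median -0.22) and the undifferentiated spermatogonia list (median -0.22). These calls are at the preset correlation, and an estimated correlation was not tried without that array.

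Of the 1052 called genes, 1046 had groups of arrays that did not overlap. Such separation held for 3502 genes (26.8%), where chance gives 10%. Withdrawal replicate 3 stood apart in control signal, with a 3' to 5' ratio of beta-actin control signal of 2.77 against 1.1 to 1.75 on the other arrays. Of the 57 named genes that were called, 38 were called under every alternative; Gfra1 lost its call without maintained replicate 3, Kif26a without withdrawal replicate 3, and Zbtb16 without withdrawal replicate 3 and without any single maintained array. The count fell to 659 without that array, to 531 without maintained replicate 2 and to 517 without maintained replicate 3. It was 313 when only the groups compared were fitted and 2297 with array weights, and the share that was higher dropped from 52.4% to 29.5% with arrays shifted to 1 median.

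**Figure D1:**
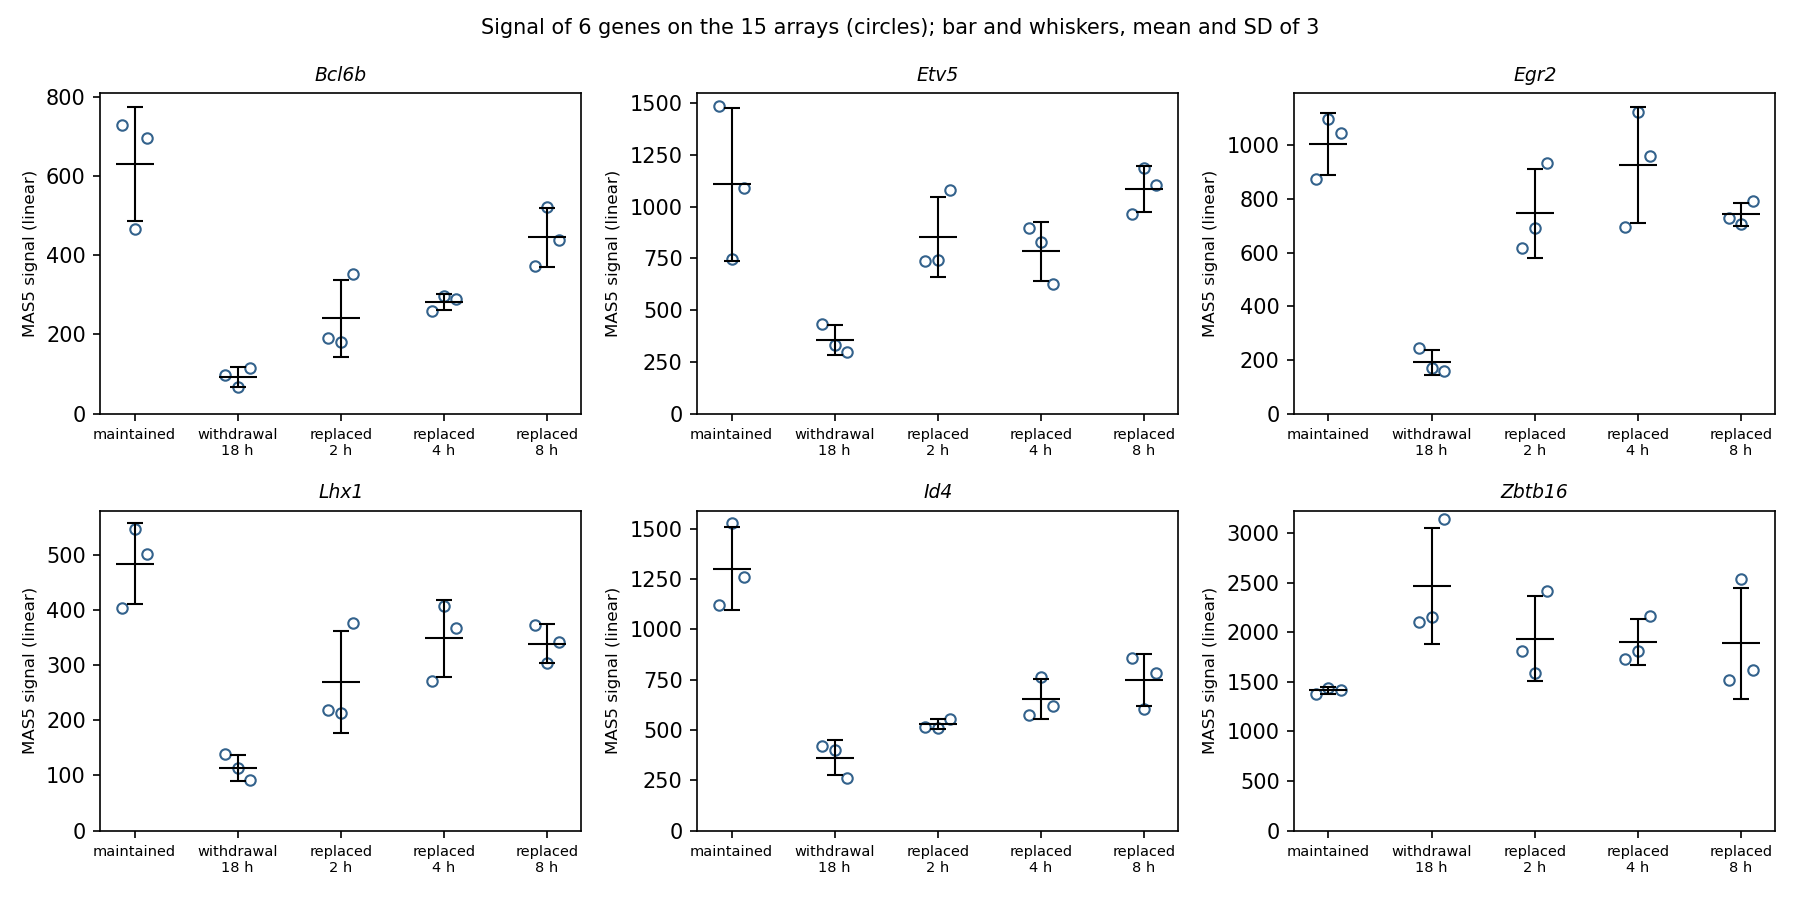
MAS5 signal (arbitrary units, linear axis) of Bcl6b, Etv5, Egr2, Lhx1, Id4 and Zbtb16 in the 5 groups; circles are single arrays, bars are means of 3 arrays and whiskers are SD. Bcl6b had a mean of 630 in maintained cultures, 92.9 after withdrawal and 445 after 8 h of replacement, while Zbtb16 had 1414 in maintained cultures and 2468 after withdrawal.

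The next comparison asked which genes responded first when both factors came back. By 2 h, immediate-early and ERK feedback genes had risen again, relative to cultures at 18 h of withdrawal. Egr1 was at 4818 ± 477 against 1448 ± 270 after withdrawal, 3.33-fold higher (adjusted p = 1.29e-05). Egr2 was at 748 ± 166 against 191 ± 46.8 (3.69-fold, adjusted p = 0.000126), Etv4 at 264 ± 76.2 against 45.5 ± 19.6 (4.6-fold, adjusted p = 0.00274), and the AP-1 gene Fos at 900 ± 113 against 352 ± 79.7 (2.52-fold, adjusted p = 0.00699). The feedback genes Spry4 (3.02-fold) and Dusp6 (2.91-fold) rose, as did Trib1 (3.51-fold), the polo-like kinase gene Plk3 (3.13-fold), Etv5 (2.34-fold), Lhx1 (2.15-fold) and Tcl1 (1.8-fold). Ier2 (log2 1.26), Junb (log2 1.07) and Zfp36 (log2 0.90) also rose. Trib1 and Plk3 lay under a signal of 30.5 after withdrawal, so their folds depend on the constant.

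In all, 15 genes were called at 2 h, 15 higher and 0 lower, 12 of them at least 2-fold, while 1054 genes had an unadjusted limma p under 0.05. All 15 had fallen on withdrawal, where 0.574 would be expected by chance, though both comparisons use the same withdrawal arrays. Of the 33 ERK genes, 10 rose (adjusted over the list alone, 14), with a median of 0.34 and an adjusted p of 5.15e-25. Of the laboratory's 8 genes, Egr2, Etv5 and Lhx1 rose (adjusted over the list alone, 6; not independent evidence), with a median of 0.82 and an adjusted p of 5.64e-13. Bcl6b was at 241 ± 97.3 and missed the threshold (log2 1.21, adjusted p = 0.0556). Cxcr4 (log2 0.53), Pou3f1 (log2 0.47), Gfra1 (log2 0.43), Ret (log2 0.64) and Id4 (log2 0.55) were not called, nor were Zbtb16 (log2 -0.34), Pou5f1 (log2 -0.32), Kit (log2 0.16), Stra8 (log2 0.96), Egr3 (log2 0.35) and Tspan8 (log2 -0.07, which became 0.01 with arrays shifted to 1 median). The other of the 2 Egr3 probe sets was called higher. The difference of Stra8, dim after withdrawal, depends on the constant.

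Cholesterol synthesis genes were all positive at 2 h. None of the 17 was called over all genes in limma, 11 were called adjusted over the list alone, and the list rose with a median of 0.45 (adjusted p = 4.71e-13). In the undifferentiated list of 27, Etv4, Etv5 and Lhx1 rose (adjusted over the list alone, 8 higher and 3 lower), with a median of 0.05 and an adjusted p of 0.000492. Each of these 3 genes is also in the ERK list or the laboratory's list, so this call is not separate evidence. Of the 27, 14 were positive and 13 negative. The ERK, laboratory, cholesterol and undifferentiated lists were also called with an estimated correlation, the last at adjusted p = 0.0396. The next 4 were not. The G1/S list was higher by a median of 0.23 (adjusted p = 1.19e-05), with 23 of 24 members positive (adjusted p = 0.172 with an estimated correlation). FOXO targets were lower by a median of -0.21 (adjusted p = 0.0184; adjusted p = 0.256 with an estimated correlation) and interferon genes by -0.18 (adjusted p = 0.04; adjusted p = 0.431 with an estimated correlation). In the fibroblasts list all 18 genes were negative, with a median of -0.37 (adjusted p = 6.72e-05), and adjusted p = 0.4 with an estimated correlation. That call ended without withdrawal replicate 3 (median -0.19) and without 2 h replicate 3 (median -0.19). Without the latter the calls of the cell cycle, G1/S list (median 0.05), the FOXO target genes (median -0.13) and the interferon response (median -0.20) ended too.

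Groups did not overlap for 1909 genes (14.6%, against 10% by chance). Etv5 and Lhx1 were among the 7 of 11 named genes that lost their call under an alternative, both of them without 2 h replicate 1, 2 or 3. The count of 15 was 9 without 2 h replicate 1, 8 without 2 h replicate 2 and 10 without withdrawal replicate 3; it was 9 without the variance trend, 5 when only the groups compared were fitted, 8 with the fibroblast covariate and 67, of which 31 were lower, with array weights.

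At 4 h of replacement, Egr2 was at 927 ± 217, 4.53-fold above withdrawal (adjusted p = 1.4e-05), and Bhlhe40 at 425 ± 82.6 against 97.4 ± 18.5 (3.87-fold, adjusted p = 1.4e-05). Bcl6b, not called at 2 h, had risen to 281 ± 19.6 (2.78-fold, adjusted p = 0.00452), and Id4 to 654 ± 99.1 (1.8-fold, adjusted p = 0.0229). Rises also included Plk3 (4.22-fold), Etv4 (3.41-fold), the ephrin receptor gene Epha2 (3.34-fold), Hs3st3b1 (3.1-fold), Nim1k (3.07-fold) and Lhx1 (2.8-fold). The largest falls were Grip2 (2.83-fold), the pro-apoptotic gene Bik (2.65-fold), Iqca (2.56-fold), Agxt (2.39-fold), Rbfox3 (2.3-fold), Cd274, which encodes the immune ligand PD-L1 (2.2-fold), the Notch target Hes5 (2.09-fold) and Tspan33 (2.04-fold). The folds of Plk3, Nim1k, Iqca and Agxt depend on the constant, with the lower group under a signal of 30.5.

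At this time 346 genes were called, 227 higher and 119 lower, and 72 changed at least 2-fold, 61 up and 11 down. Of the ERK list, 16 of 33 rose (adjusted over the list alone, 21; median 0.75, adjusted p = 2.81e-21), among them Dusp6 (2.68-fold) and Spry4 (2.53-fold). Of the laboratory's list, 6 of 8 rose (adjusted over the list alone, 6; not independent evidence), namely Bcl6b, Egr2, Lhx1, Etv5 (2.16-fold), Cxcr4 (2.06-fold) and Pou3f1 (1.99-fold). Its median was 1.08 (adjusted p = 5.75e-10). Of cholesterol synthesis genes, 7 of 17 rose (adjusted over the list alone, 11), with a median of 0.57 and an adjusted p of 9.22e-12. Msmo1 reached 2014 ± 272 (2.18-fold) and Idi1 3350 ± 407 (1.72-fold), and Cyp51 and Lss rose 1.68-fold and 1.67-fold. These 3 lists were also called with an estimated correlation.

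Fibroblast genes rose as well: 6 of 18 were higher at 4 h (adjusted over the list alone, 12), with a median of 0.81 and an adjusted p of 3.56e-11, or adjusted p = 0.176 with an estimated correlation. The collagen genes Col5a2 (2.52-fold) and Col3a1 (2.28-fold), Timp3 (2.23-fold) and Postn (2-fold) were examples, and 11 of these fibroblasts list genes were called without withdrawal replicate 3. In the FOXO list, Fbxo32 (1.86-fold), Ddit4 (1.85-fold), Bcl6 (1.63-fold) and Txnip (1.56-fold) fell, 4 of 21 (adjusted over the list alone, 5), and the list was not called (adjusted p = 0.179). Of 27 undifferentiated genes, 5 rose and Neurog3 (log2 -0.92) and Sox3 (log2 -0.86) fell (adjusted over the list alone, 9 and 4); the median was -0.18 with a mean of 0.13 and an upward test (adjusted p = 0.281). Fgf9 rose 2.23-fold and Tcl1 1.69-fold, while Slc2a1 (1.6-fold) and Trib3 (1.59-fold) fell. Of the genes named in every comparison, Gfra1 (log2 0.21), Ret (log2 -0.42), Zbtb16 (log2 -0.35), Egr3 (log2 0.15), Kit (log2 0.26), Stra8 (log2 0.37), Tspan8 (log2 -0.12, or 0.15 with the mean of its probe sets) and Pou5f1 (log2 -0.27) were not called, although the other of the 2 Egr3 probe sets was called higher. Ret signal was 757, 369 and 278 on 4 h replicates 1, 2 and 3. The 3' to 5' ratios of beta-actin control signal on these arrays were 1.12, 1.52 and 1.75.

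The groups of all 346 called genes were separate, as were those of 2798 genes (21.4%, against 10% by chance). Of 39 named genes that were called, 5 were called under every alternative; Id4 lost its call without 4 h replicates 2 or 3, and Etv5 without 4 h replicate 2. The count was 159 without withdrawal replicate 1, 156 without withdrawal replicate 2, 620 without 4 h replicate 1, 56 without 4 h replicate 2 and 86 without 4 h replicate 3. It was 182 without the filter, 208 without the variance trend, 13 when only the groups compared were fitted, 1609 with array weights, 190 with the fibroblast covariate and 734 with the beta-actin covariate, and the share that was higher went from 65.6% to 89.5% with arrays shifted to 1 median.

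After 8 h of replacement, Bcl6b had reached 445 ± 74.8, 4.28-fold above withdrawal (adjusted p = 0.000242). Etv5 was at 1085 ± 112 (3-fold, adjusted p = 0.00126) and Dusp6 at 1216 ± 158 (3.56-fold, adjusted p = 0.00126). Id4 was at 747 ± 129 (2.04-fold, adjusted p = 0.00654). Genes that had risen on withdrawal fell: Camk2n1 to 281 ± 32.8 (3-fold lower), Zmym3 to 275 ± 107 (2.98-fold lower), Ddit4 to 960 ± 306 (3.04-fold lower) and Esr1 to 30.9 ± 12.2 (2.94-fold lower). Other rises were Etv4 (4.3-fold), Epha2 (3.77-fold), Egr2 (3.72-fold), Nim1k (3.2-fold), Plk3 (3.12-fold) and Bhlhe40 (3.07-fold). Other falls were the meiotic cohesin gene Rec8 (3.16-fold), Sox6 (3.07-fold), Crispld2 (2.95-fold) and Cd274 (2.93-fold). The lower group lay under a signal of 30.5 for Nim1k, Plk3, Rec8 and Sox6.

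Here 313 genes were called, 170 higher and 143 lower, with 88 at least 2-fold, 60 up and 28 down. Of 33 ERK genes, 15 rose (adjusted over the list alone, 19; median 0.61, adjusted p = 3.27e-17), among them Spry4 (3.02-fold). Of the laboratory's 8, Bcl6b, Etv5, Egr2, Lhx1 (2.75-fold) and Cxcr4 (2.36-fold) rose (adjusted over the list alone, 5; not independent evidence), with a median of 1.35 and an adjusted p of 8.15e-12. Only these 2 lists were called with an estimated correlation. Among cholesterol synthesis genes only Msmo1 rose (1.56-fold; adjusted over the list alone, 1), and the list median was 0.27 (adjusted p = 0.00568; adjusted p = 0.327 with an estimated correlation). FOXO targets were lower by a median of -0.16 (adjusted p = 0.0381; adjusted p = 0.385 with an estimated correlation), with Ddit4 and Txnip (1.77-fold) called (adjusted over the list alone, 3). Of 27 undifferentiated genes, 6 rose and Upp1 (log2 -1.22) and Foxo1 (log2 -0.79) fell (adjusted over the list alone, 8 and 6), with a median of -0.07, a mean of 0.20 and an upward test (adjusted p = 0.302).

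Of 18 fibroblast genes, 4 rose at 8 h (adjusted over the list alone, 10), with a median of 0.70 (adjusted p = 2.02e-10; adjusted p = 0.274 with an estimated correlation). They were Col5a2 (2.29-fold), Col3a1 (2.12-fold), Postn (2.1-fold) and the intermediate filament gene Vim (2.03-fold), and without withdrawal replicate 3 the number called was 10. Of 5 Leydig and peritubular genes, Cyp11a1, a steroidogenic enzyme gene, rose 2.46-fold and Pdgfra 2.03-fold (adjusted over the list alone, 2; median 0.33, adjusted p = 0.0316; adjusted p = 0.321 with an estimated correlation). With the fibroblast covariate that median was -0.00. Of the 11 genes listed for Leydig and peritubular cells, only these 5 were tested. Of the other lists of cell markers, Sertoli cells (median 0.17, adjusted p = 0.302) and endothelial and blood cells (median 0.27, adjusted p = 0.302) were not called. G2/M genes were lower by a median of -0.11 without any single call in limma (adjusted p = 0.0381; adjusted p = 0.531 with an estimated correlation), and 0.03 with the fibroblast covariate. Also called were rises of Tcl1 (2.08-fold), Hk2 (1.82-fold), Ccnd2 (1.72-fold) and Dppa4 (1.44-fold), and falls of Bik (1.9-fold), Trib3 (1.75-fold), Fgfr4 (1.66-fold), Dnmt3b (1.61-fold) and Hk1 (1.42-fold). Pou3f1 (log2 0.21), Gfra1 (log2 0.38), Ret (log2 0.45), Zbtb16 (log2 -0.40), Stra8 (log2 0.92), Kit (log2 0.34), Pou5f1 (log2 -0.42), Egr3 (log2 0.47) and Tspan8 (log2 0.30) were not called, although other probe sets of Egr3 (log2 1.69) and Tspan8 (log2 1.23) were higher. Conversely, a second probe set of Egr2 (log2 0.64), both other probe sets of Id4 (log2 0.49 and 0.52) and 1 of Etv5 (log2 1.62) were not called. Stra8 was dim after withdrawal, so its difference depends on the constant.

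Groups were separate for 312 of the 313, and for 2808 of all genes (21.5%, against 10% by chance). Of 38 named genes that were called, 18 were called under every alternative. The count was 204 without withdrawal replicate 1, 189 without withdrawal replicate 2, and 125, 100 and 110 without 8 h replicates 1, 2 and 3. It was 121 when only the groups compared were fitted, 1192 with array weights and 144 with the fibroblast covariate.

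Genes that fell on withdrawal were often those that rose on replacement. Of 501 that fell and 300 that rose at 1 or more replacement times, 140 were shared, where 11.5 would be expected by chance. Of 551 that rose on withdrawal and 225 that fell on replacement, 135 were shared, where 9.48 would be expected. Genes that fell both times numbered 0 (8.62 expected) and genes that rose both times 2 (12.6 expected). By time, 106 of the 227 genes that rose at 4 h and 89 of the 170 at 8 h had fallen on withdrawal. Of the 119 and 143 genes that fell at these times, 72 and 97 had risen. The rises at 4 h and 8 h shared 97 genes and the falls 37, in comparisons with the same withdrawal arrays.

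The same 3 withdrawal arrays stand on both sides of these overlaps, which by itself makes the differences move together. In 100 simulated draws with no true differences and shared arrays, both overlaps had a mean of 0 and a highest value of 0. Without true differences the adjusted threshold leaves hardly any gene to be called, so overlaps near 0 follow whether or not arrays are shared. These draws therefore do not show how much of the real overlaps the sharing gives. Across genes, which are not independent replicates, the correlation of maintained minus withdrawal with replacement minus withdrawal was 0.551 at 2 h, 0.674 at 4 h and 0.594 at 8 h, against 0.5 in simulation. The 2 differences had the same sign for 69.5%, 76.2% and 67.8% of genes at these times, against 66.7% in simulation. By this measure, 2 h and 8 h lay close to what shared arrays give alone. The simulation does not hold true changes measured with shared error, so part of the overlap may come from the sharing, and 3 arrays are too few to be divided between the comparisons. The shared falls and rises counted 480 and 503 with array weights, the first 234 with the beta-actin covariate, and the second 86 with arrays shifted to 1 median and 87 without the variance trend. The lowest and highest of these overlaps with 1 array left out were 89 and 186, and 65 and 206.

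A comparison of 8 h of replacement with maintained cultures asked how far expression had come back. Etv5 (1085 ± 112 against 1108 ± 370) was not called, at a log2 difference of 0.02 that turned to -0.13 with arrays shifted to 1 median. Bcl6b (log2 -0.47, adjusted p = 0.311), Egr2 (log2 -0.43, adjusted p = 0.27) and Lhx1 (log2 -0.49, adjusted p = 0.248) were not called either; a missed threshold does not show that levels were equal. Sox2 was at 47.3 ± 5.52 against 224 ± 10.2 (3.8-fold lower, adjusted p = 0.000822). Pou3f1, which had been at 338 ± 56.4 at 4 h, was at 188 ± 8.02 against 379 ± 66.4 (1.92-fold lower, adjusted p = 0.0115); 4 h and 8 h were not compared by a test. Id4 (log2 -0.79, adjusted p = 0.0561) and Cxcr4 (log2 -0.90, adjusted p = 0.0747) missed the threshold. Other falls were the keratin gene Krt19 (5.12-fold), Skor1 (3.02-fold), Snap91 (2.8-fold), Cd24a (2.61-fold), Slc2a3 (2.5-fold) and the polyamine enzyme gene Odc1 (1.73-fold). The largest rises were the acute-phase gene Serpina3n at 552 ± 87.4 against 134 ± 90.9 (4.57-fold), the mast cell tryptase gene Tpsb2 (3.28-fold), Adh1 (3.14-fold), Serpinb1a (3.11-fold) and the mast cell chymase gene Mcpt4 (2.99-fold). The lower group lay under a signal of 30.5 for Krt19 and Cd24a.

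In this comparison 63 genes were called, 36 higher and 27 lower, with 35 at least 2-fold, 23 up and 12 down. Of the 27 that were lower, 23 had fallen on withdrawal, and of the 36 that were higher, 18 had risen. Both comparisons use the same maintained arrays, which by itself favours such overlap, and no simulation was made for it. Cholesterol synthesis genes were below maintained cultures: Idi1 was called (1.88-fold lower) and 16 of 17 adjusted over the list alone, with 17 of 17 negative and a median of -0.58 (adjusted p = 5.66e-15; adjusted p = 0.013 with an estimated correlation). No other list call held with an estimated correlation. The G1/S list was lower by a median of -0.30 (adjusted p = 2.05e-08; adjusted p = 0.134 with an estimated correlation), with 9 of 24 genes called over the list alone and 0 over all genes in limma, where 2230 genes had an unadjusted p under 0.05. Glycolysis genes, with Slc2a3 called, were lower by -0.33 (adjusted p = 1.84e-05; adjusted p = 0.17 with an estimated correlation). Smaller downward shifts were those of G2/M (median -0.11, adjusted p = 0.00496; 0.251 as adjusted p with an estimated correlation), ATF4 (-0.14, adjusted p = 0.0115; 0.19) and ribosome genes (-0.04, adjusted p = 0.044; 0.424), the last turning to 0.03 with quantile normalization. The laboratory's list was lower by -0.45 (adjusted p = 0.00517; adjusted p = 0.17 with an estimated correlation), with Pou3f1 called (adjusted over the list alone, 2; not independent evidence), but its median was 0.00 with the fibroblast covariate, where that of G2/M was 0.05.

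Differentiating spermatogonia genes were higher by a median of 0.31 (adjusted p = 0.0463; adjusted p = 0.17 with an estimated correlation), with Sohlh1 called (2-fold; adjusted over the list alone, 5 higher and 1 lower). Egr4 was 1.82-fold higher. Fibroblast genes were higher by 0.60 (adjusted p = 1.11e-06; adjusted p = 0.19 with an estimated correlation), with 9 of 18 called over the list alone. Leydig and peritubular genes were higher by 0.88 (adjusted p = 0.00224; adjusted p = 0.134 with an estimated correlation), with Cyp11a1 (2.65-fold) and Pdgfra (2.6-fold) called. Sertoli cell genes were higher by 0.40 (adjusted p = 0.0239; adjusted p = 0.134 with an estimated correlation), with 2 called over the list alone. Cyp17a1, Hsd3b1, Myh11 and Cnn1 of the Leydig and peritubular list were on the array but too dim to be tested. The same held for Amh, Cst9 and Cldn11 of the Sertoli list. The shifts of these lists rest on their brighter members and do not by themselves show RNA of these cells. Gfra1 (log2 -0.49), Zbtb16 (log2 0.38), Kit (log2 0.44), Ret (log2 0.40), Egr3 (log2 0.48), Tspan8 (log2 0.16), Pou5f1 (log2 -0.07) and Stra8 (log2 0.26) were not called.

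All 63 called genes had separate groups, as had 3479 of all genes (26.6%, against 10% by chance). Of 18 named genes that were called, 0 were called in limma under every alternative, a tally fixed by the fibroblast covariate, which called 0 genes in all. The count was 154, 26 and 13 without maintained replicates 1, 2 and 3, 27, 15 and 13 without 8 h replicates 1, 2 and 3, and 276 without withdrawal replicate 3, which is in neither group but enters the spread. It was 180 when only the groups compared were fitted, 1280 with array weights, 333 with the beta-actin covariate and 0 with the fibroblast covariate. The share that was higher, 57.1%, was 44.7% with quantile normalization and 21.7% with arrays shifted to 1 median, a setting that moved the median of all genes from 0.06 to -0.08 here and from 0.04 to -0.09 between 8 h and 2 h.

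The last comparison set late against early replacement. At 8 h the fibroblasts list, which includes Col3a1, was higher than at 2 h (adjusted p = 0.117 with an estimated correlation). Col3a1 was at 3091 ± 416 against 1030 ± 367 (3.1-fold, adjusted p = 0.00311), Ptn, a secreted growth factor, at 1508 ± 347 against 391 ± 103 (3.77-fold, adjusted p = 0.00151), Svep1 at 97.3 ± 20.1 against 12.6 ± 9.01 (4.04-fold, adjusted p = 0.00311) and the matrix proteoglycan gene Ogn at 114 ± 9.68 against 21.5 ± 15.1 (3.69-fold, adjusted p = 0.00209). Cdc42ep2 (3.99-fold) and Pyroxd2 (3.75-fold) were also among the largest rises. Egr1, the early gene, fell from 4818 ± 477 to 2889 ± 291 (1.66-fold, adjusted p = 0.0138), and Arrdc3 was 2.45-fold lower (adjusted p = 4.39e-05). Other falls were Glis1 (2.83-fold), Gga1 (2.67-fold), Crispld2 (2.53-fold) and the kinase gene Pim3 (2.42-fold). The folds of Svep1, Ogn, Cdc42ep2, Pyroxd2 and Glis1 depend on the constant, with the lower group under a signal of 30.5.

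Between these times 242 genes were called, 193 higher and 49 lower, with 99 at least 2-fold, 87 up and 12 down. Of 18 fibroblast genes, 9 rose (adjusted over the list alone, 17), with a median of 1.04 and an adjusted p of 3.76e-19; adjusted p = 0.117 with an estimated correlation. Postn (2.97-fold), Timp3 (2.75-fold) and Col5a2 (2.65-fold) were among them, and Thy1, a surface marker of fibroblasts and of stem cells, rose 1.95-fold. The number of fibroblast genes called was 14 without withdrawal replicate 3 and 4 without 2 h replicate 3. Leydig and peritubular genes were higher by 0.97 (adjusted p = 0.000857), with Pdgfra (2.5-fold) and Cyp11a1 (2.45-fold) called (adjusted over the list alone, 3), and Sertoli cell genes by 0.49 (adjusted p = 0.015), with Rhox5 called (1.8-fold; adjusted over the list alone, 3). Each of these had adjusted p = 0.117 with an estimated correlation. Here too the dim markers of both lists, named above, were not tested. The p53 targets Zmat3 (2.15-fold), Cdkn1a (1.98-fold) and Ccng1 (1.84-fold) rose, 3 of 19 (adjusted over the list alone, 6), although that list had a median of -0.01, a mean of 0.18 and no call. Csf1 (1.93-fold), Hk2 (1.74-fold) and Ier3 (1.6-fold) rose too.

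Growth-related lists were lower at 8 h than at 2 h, calls that did not hold with an estimated correlation: G2/M by -0.19 (adjusted p = 0.000272; adjusted p = 0.334 with an estimated correlation), G1/S by -0.15 (adjusted p = 0.0114; 0.391), cholesterol synthesis by -0.11 (adjusted p = 0.00897; 0.383) and ribosome genes by -0.11 (adjusted p = 0.00897; 0.391). In the last, Odc1 (1.45-fold) and Dkc1 (1.38-fold) fell, also when adjusted over the list alone; the other 3 lists had no call in limma. With the fibroblast covariate the medians of G2/M, G1/S and cholesterol genes were 0.16, 0.10 and 0.14. Without 2 h replicate 3, the calls of the G1/S, cholesterol, ribosome and Sertoli lists ended. Ddit4 (2.02-fold), Txnip (1.59-fold), Dmrt1 (1.48-fold) and Atf4 (1.47-fold) fell as well. The ERK list as a whole was not called (median 0.12, mean 0.07, adjusted p = 0.862), and Bcl6b missed the threshold (log2 0.89, adjusted p = 0.0621). Also not called were Cxcr4 (log2 0.71), Id4 (log2 0.48), Tspan8 (log2 0.37), Etv5 (log2 0.36), Lhx1 (log2 0.36), Kit (log2 0.18), Egr3 (log2 0.12) and Egr2 (log2 0.01), of which the last pair turned negative with arrays shifted to 1 median. The same held for Pou3f1 (log2 -0.26), Ret (log2 -0.19), Pou5f1 (log2 -0.10), Stra8 (log2 -0.05), Zbtb16 (log2 -0.05) and Gfra1 (log2 -0.05), of which Zbtb16 and Gfra1 turned positive with quantile normalization. Egr3 was called lower with a constant of 64 (log2 -0.71).

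The fibroblast list lay, on average, -0.60 ± 0.38 from each gene's mean over all arrays at 2 h, 0.50 ± 0.11 at 4 h and 0.45 ± 0.14 at 8 h. In maintained cultures it lay at -0.13 ± 0.15 and after withdrawal at -0.23 ± 0.36. All 242 called genes had separate groups, as had 3344 of all genes (25.6%, against 10% by chance). Of 31 named genes that were called, 1 was called under every alternative, a tally limited by the fibroblast covariate, which called 2 genes in all. The count was 107 without 2 h replicate 2, 73 without 2 h replicate 3, 103, 61 and 95 without 8 h replicates 1, 2 and 3, and 430 without withdrawal replicate 3. It was 498 when only the groups compared were fitted, 904 with array weights, 470 with the beta-actin covariate, 137 (74 higher and 63 lower) with arrays shifted to 1 median and 2 with the fibroblast covariate, under which Csf1 and Cyp11a1 turned negative.

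**Figure D2:**
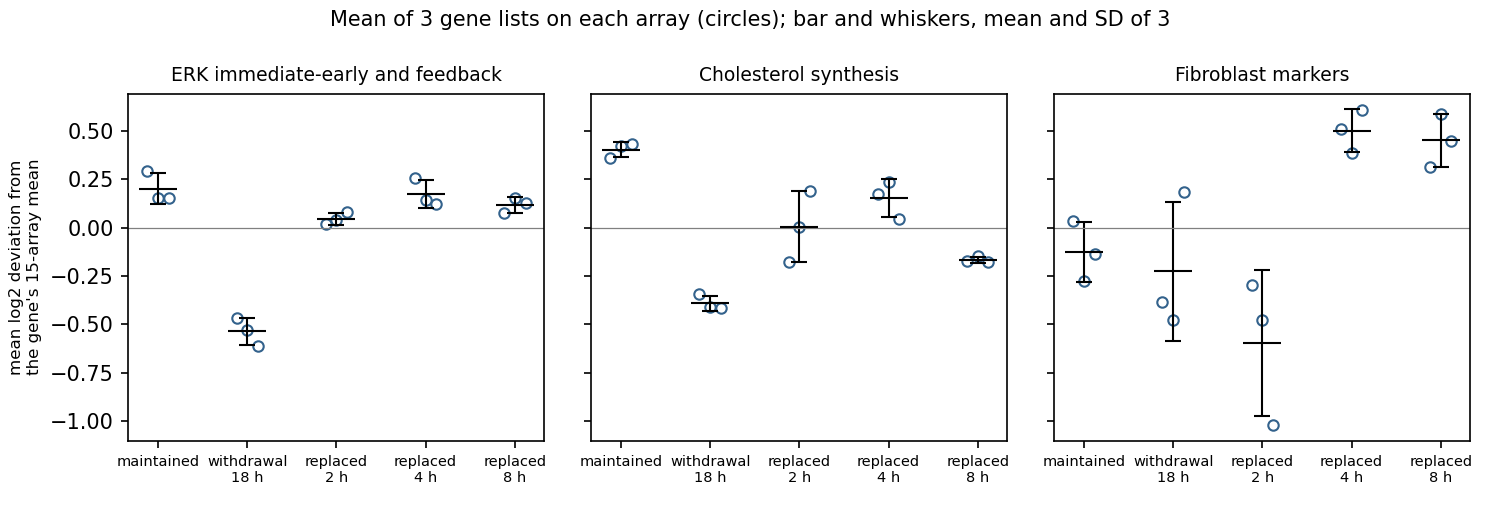
Mean log2 deviation of the tested genes of the ERK, cholesterol synthesis and fibroblast lists from each gene's mean over 15 arrays, by group; each circle is 1 array. The ERK list lay at -0.54 ± 0.07 (mean ± SD, n = 3) after withdrawal and at 0.05 ± 0.03 after 2 h of replacement, while the fibroblast list lay at -0.60 ± 0.38 at 2 h and at 0.50 ± 0.11 at 4 h.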

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

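The tests chosen only after their result was seen were that of the presence of GDNF and all tests of withdrawal replicate 3, and those that use the fibroblast covariate, the beta-actin covariate or fits without withdrawal replicate 3 for lists are alternatives added after the data were examined.

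Fibroblast genes differed between replacement times that share the same withdrawal arrays: the list lay higher at 8 h than at 2 h by a median of 1.042, with 9 of 18 genes called, or 4 of 18 without 2 h replicate 3 (list adjusted p = 3.76e-19; adjusted p = 0.117 with an estimated correlation). Array scaling was argued against, since the smaller median under the 2 scalings was 0.913. The presence of GDNF alone, which maintained cultures also had, was argued against because the list mean was higher at 8 h than in maintained cultures by 0.577 (SE 0.208). This argument is limited: in that comparison camera did not call the list with an estimated correlation (adjusted p = 0.19), and 0 of its genes were called over all genes. A larger share of fibroblast RNA stays open as a candidate explanation: a second list of 20 fibroblast genes, not used before, was higher by a median of 0.974, with 13 called (adjusted p = 0.0147 with an estimated correlation), and Col3a1 reached 3091 ± 416. The p-value of the second list was adjusted over the few added lists only, and that of the first over the 20 fixed lists. The adjusted values of these 2 lists are therefore not directly comparable. The time of replacement, which the design names, also stays open and untested as a regulator of these genes, and Thy1 of the first list is also in the undifferentiated list.

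Withdrawal replicate 3 stood apart in control signal that no comparison uses: its 3' to 5' ratio for beta-actin was 2.77, against 1.1 to 1.75 on the other 14 arrays. A wrong group label was argued against by its ERK list mean, which lay 0.111 from that of the other withdrawal arrays and at least 0.654 from the mean of any other group. Degraded or short labelled RNA stays open, since all 3 of the 3 control transcripts had ratios above the other arrays, Gapdh at 1.77 against 0.713 to 1.05 and pyruvate carboxylase at 6.43 against 1.18 to 3.16. RNA of other cells may also contribute: the array's fibroblast list mean lay 0.569 above the higher of the other withdrawal arrays, where the pooled SD was 0.2. The design gives no biological explanation for 1 array, and none was tested. High ratios were not confined to this array. The next highest beta-actin ratios were those of 4 h replicates 3 and 2, at 1.75 and 1.52, with 1.12 on 4 h replicate 1. Apart from the beta-actin covariate and fits with 1 array left out, an effect of RNA quality on the 4 h comparison was not tested.

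Cholesterol synthesis genes were lower after withdrawal by a median of -0.756, with a list mean of -0.39 ± 0.04 against 0.40 ± 0.04 in maintained cultures. Array scaling was argued against, with a weaker median of -0.695 under the 2 scalings, as was a changed share of fibroblast RNA, with -0.813 under the covariate. The RNA quality of withdrawal replicate 3 was argued against in the same way, with a weaker median of -0.751 without that array or with the beta-actin covariate. That these transcripts respond to the joint withdrawal of GDNF and GFRalpha1 stays open; no test here parts the factors from each other or from other effects of the withdrawal, and sterol synthesis itself was not measured.

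Across all genes, 242 differed between 8 h and 2 h of replacement, a test of the difference between these effects, since both were set against the same withdrawal arrays. Among 4154 probe sets with no single gene name, which the comparisons by gene leave aside, 108 (2.6%) passed on withdrawal, 56 higher and 52 lower.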

How the results depend on the processing

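The alternatives chosen after the data were seen were array weights, the fibroblast and beta-actin covariates, and leaving out withdrawal replicate 3 (for 8 h against maintained, 8 h against 2 h and lists) or 2 h replicate 3 (for lists). Named genes that were called on withdrawal gave 1191 values under alternatives, of which 1117 kept direction and call, 74 kept direction only and 0 reversed. At 2, 4 and 8 h against withdrawal, 175 of 229, 606 of 813 and 655 of 793 kept both, with 0 reversals. For 8 h against maintained cultures this held for 302 of 390, with 0 reversals, and for 8 h against 2 h for 505 of 676, with 4 reversals. Dim genes are limited by signal over background, since the filter lies at a signal of 30.5. Replicate numbers were not treated as pairs, since the labels give no shared culture or day. After removal of group means, 7 of 30 pairs of arrays with the same number had an r over 0.1 (median -0.0165, lowest -0.15, highest 0.363). For other numbers this held for 10 of 60 pairs, with a highest r of 0.232. Yet 11 of 15 arrays, though not all, correlated best with an array of their own number. That is more often than numbers without meaning would give, so shared handling by number is not excluded. The replicate block gave 1121, 16, 372, 316, 56 and 217 genes in the order withdrawal against maintained, 2, 4 and 8 h against withdrawal, 8 h against maintained and 8 h against 2 h, which is the order used throughout.

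With 1 array left out, the counts ran from 517 to 1014, from 8 to 16, from 56 to 620, from 100 to 353, from 13 to 276 and from 61 to 430, with fewer arrays in each fit. Genes that fell and then rose ran from 89 to 186, and those that rose and then fell from 65 to 206. Fits of only the groups compared gave 313, 5, 13, 121, 180 and 498, with fewer arrays and degrees of freedom. Array weights gave 2297, 67, 1609, 1192, 1280 and 904 and overlaps of 480 and 503. Withdrawal replicate 3 had the lowest weight, 0.22, but the cause of the change in counts was not tested. Without the variance trend, 9 genes were called at 2 h and 208 at 4 h, and the second overlap was 87, the cause of which was not tested; without the filter 182 were called at 4 h, where more genes were tested. With arrays shifted to 1 median, 137 genes differed between 8 h and 2 h and the second overlap was 86; the cause was not tested. The fibroblast covariate gave 8, 190 and 144 genes at 2, 4 and 8 h against withdrawal, 0 for 8 h against maintained (limma) and 2 for 8 h against 2 h; the covariate itself differs between these groups. The beta-actin covariate gave 734 genes at 4 h, 333 for 8 h against maintained, 470 for 8 h against 2 h and 234 for the first overlap, and here too the cause was not tested. List calls numbered 43, and 13 with an estimated correlation, which is larger than the preset for most lists. For all other settings and counts the value lay within 1.5 times that reported.

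Lists that reversed on withdrawal were not called. The undifferentiated list was 0.03 with 60% of probe sets left out. Quantile normalization gave GDNF and FGF genes -0.038, G2/M 0.032 and interferon -0.019, and shifting to 1 median gave GDNF and FGF genes -0.081, ribosome -0.059 and interferon -0.013. G2/M was 0.069 and ribosome -0.068 with array weights, and 0.063 and -0.031 with the beta-actin covariate. Without withdrawal replicate 3, meiotic genes were at 0.042, G2/M at 0.108 and ribosome at -0.073. The only other array left out for lists was 2 h replicate 3, which is in neither group. Without it the medians were -0.054, -0.009 and 0.034. Of called lists, ribosome for 8 h against maintained was 0.033 with quantile normalization. The fibroblast covariate gave G2/M 0.033 and Leydig -0.001 for 8 h against withdrawal, the laboratory's list 0.002 and G2/M 0.05 for 8 h against maintained, and G1/S 0.105, G2/M 0.159 and cholesterol 0.14 for 8 h against 2 h. The causes were not tested.

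Among single genes, 4 called ones reversed, all between 8 h and 2 h with the fibroblast covariate: Thy1 (-0.262), Csf1 (-0.082), Timp3 (-0.031) and Cyp11a1 (-0.117). Thy1 and Timp3 are members of the list whose mean is the covariate, so their reversal follows by construction and shows no dependence on processing; values of other members under that covariate, which are among the counts of named genes, are circular in the same way. Genes not called in the report reversed as follows, and the cause was not tested except that probe sets of Egr3, Tspan8, Ret, Egr2 and Gfra1 differ from each other. Of these reversed values, 3 were called, all of Egr3: on withdrawal with a constant of 64 and with the mean of probe sets, and for 8 h against 2 h with a constant of 64. Egr3 on withdrawal was -0.859 with a constant of 64, -0.058 with quantile normalization, -0.08 with 1 median and -0.761 with the mean of probe sets, and from -0.253 to 0.288 with 1 array left out. Between 8 h and 2 h it was -0.714, -0.012 and -0.403 with a constant of 64, 1 median and the mean of probe sets. At 4 h it ran from -0.097 to 0.466 with 1 array left out. Ret on withdrawal was 0.316 with array weights, 0.424 with the beta-actin covariate and from -0.311 to 0.362 with 1 array left out. Ret was 0.136 at 4 h and -0.013 for 8 h against maintained with the mean of probe sets, -0.192 at 8 h with the beta-actin covariate, and 0.317 for 8 h against 2 h with the fibroblast covariate. Tspan8 at 2 h was 0.005 with 1 median and 0.201 with the mean of probe sets, which gave 0.145 at 4 h and -0.179 for 8 h against maintained. Etv5 for 8 h against maintained was -0.125 with 1 median, -0.033 with array weights, -0.028 with the beta-actin covariate and from -0.232 to 0.256 with 1 array left out, and Lhx1 was 0.041 with the fibroblast covariate. Between 8 h and 2 h, Egr2 was -0.118 with 1 median and -0.103 with the mean of probe sets. Gfra1 was 0.044 with quantile normalization, 0.271 with the mean of probe sets, 0.116 with array weights and 0.528 with the fibroblast covariate, which gave Pou3f1 0.091 and Kit -0.056. Zbtb16 was 0.037 with quantile normalization and 0.032 with array weights. With 1 array left out, Egr2 ran from -0.115 to 0.18, Gfra1 from -0.231 to 0.243, Zbtb16 from -0.282 to 0.117 and Stra8 from -0.171 to 0.137.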

Other observations

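The hypotheses here were formed after the genes named in them were seen, while the lists and bounds used to test them were written before the test values were known.

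Mast cell protease genes were higher at 8 h of replacement than in maintained cultures. Cma1 was at 938 ± 194 against 322 ± 22.3 (2.79-fold), Cpa3 at 1227 ± 211 against 552 ± 72.1 (2.18-fold), and Mcpt4 and Tpsb2, named in the report, were 2.99-fold and 3.28-fold higher. At 2 h of replacement Cma1 was at 563 ± 67.2. RNA of mast cells may account for this: of 10 other mast cell genes, 10 were positive, with a median of 0.612 (adjusted p = 5.38e-06; adjusted p = 0.00986 with an estimated correlation), although only 1 was called by itself. All comparisons of single mast cell genes rest on 3 arrays a group, and mast cells were not in the labels of the cultures.

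Adm, a vasoactive peptide gene, was 2.97-fold higher at 8 h than at 2 h (249 ± 51.9 against 72.8 ± 13.6), and Ankrd37 was 2.48-fold higher (354 ± 61.6 against 135 ± 33.1); both are known to respond to low oxygen. A hypoxia response was argued against, since 15 other hypoxia genes had a median of 0.055 and no call of the list (adjusted p = 0.744). Hsph1 (1.63-fold) and Chordc1 (1.8-fold), cochaperone genes, were also higher at 8 h than at 2 h. A heat shock response was argued against by 14 other heat shock genes, with a median of -0.03 and no call of the list (adjusted p = 0.744).

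Groupings of the arrays other than the real one were tried for each count. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave the highest count. The real and highest other counts were 1052 and 1 on withdrawal, 15 and 0 at 2 h, 346 and 97 at 4 h and 313 and 0 at 8 h against withdrawal, 63 and 0 for 8 h against maintained, and 242 and 1 for 8 h against 2 h. A wrong split mixes the real groups, so any real difference between them widens the spread and lowers its count. The other counts are therefore not those of data without differences. Over all 15 arrays, 100 assignments to 5 groups of 3 were drawn, the real one included. For genes that fell and then rose, 2 of the 100 gave as many as the real 140, the highest other giving 238. For genes that rose and then fell, 2 of 100 gave as many as the real 135, the highest other giving 197, and for list calls 1 of 100 did, the real one with 43 against 42. The share was under 0.05 in these 3 cases, which does not exclude chance. Another random assignment gave a larger overlap each time, and 1 came within reach of the real number of list calls. Shuffling also treats the arrays as independent, which the labels do not state.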
